A study of Mus musculus with 30 samples.

How the data were processed

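The series holds RNA sequencing of primary melanomas from Dct::TVA mice, a strain in which cells that express Dct carry an avian virus receptor, so that engineered viruses infect them. Per the labels, frozen tumours in embedding medium were macrodissected, RNA was extracted with a DNase step, ribosomal RNA was depleted, and stranded total RNA libraries were prepared. The labels name 30 tumours in 5 genotypes. The submitters' notes leave out 8 of these samples, and the count table holds the other 22, which are 22 independent animals as labelled.

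The deposited table holds raw counts, as whole numbers per Ensembl gene with 1 column per library, and no normalization by the authors. Per the labels, the genome build was mm10, and the processing notes name DESeq2 without a version or a model. The aligner's settings, the counter, the annotation release and the strand setting are not stated. The table has 49671 genes, of which 49326 were matched by identifier to a symbol in GENCODE M21 on the same build; the other 345 held 0.0521% of the counts.

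Libraries were grouped by the genotype label. Cdkn2a_null is BRAFV600E;Cdkn2a-/- (n = 5), and Pten_null is BRAFV600E;Cdkn2a-/-;Pten-/- (n = 5). AKT1_E17K, AKT2_E17K and AKT3_E17K are the Pten_null genotype with the E17K mutant of the named AKT kinase (n = 4 each). Replicate numbers follow the order of the labels and pair no samples.

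Changed genes were called with edgeR 4.0.16 in R 4.3.3, with limma 3.58.1 for list tests. All 22 libraries entered 1 fit with 1 coefficient per group, TMM factors, filterByExpr, robust estimateDisp and glmQLFit, and glmQLFTest. The filter left 17686 genes, and a gene passed at a Benjamini-Hochberg adjusted p under 0.05 over these. Fold changes are given as log2 with their standard error (SE), and levels as CPM (counts scaled to the library size with TMM) with their standard deviation (SD). The comparisons were Pten_null with Cdkn2a_null, each AKT group with Pten_null, the AKT groups with each other, the mean of the 3 AKT groups with Pten_null, and a joint test of any difference between the 5 groups.

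There were 15 pathway lists and 13 lists of cell type markers, tested with camera at a preset correlation of 0.01, with camera at an estimated correlation, and with fry, adjusted over the 28 lists within a comparison. The pathway lists were melanocyte pigmentation, neural crest and dedifferentiated melanoma, MAPK pathway output, FOXO targets, sterol and fatty acid synthesis, glycolysis and hypoxia, amino acid response, oxidative phosphorylation, focal adhesion and integrins, extracellular matrix, cell cycle, MYC and ribosome biogenesis, p53 targets, interferon response and antigen presentation. The marker lists were T and NK cell, macrophage, neutrophil, B and plasma cell, endothelial, fibroblast, pericyte and smooth muscle, keratinocyte, hair follicle, skeletal muscle, adipocyte, Schwann cell and nerve, and red blood cell. A count "adjusted over the list alone" uses Benjamini-Hochberg over the members of that list.

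The genes to name were set by a rule. It takes the targeted genes Braf, Cdkn2a, Pten, Akt1, Akt2 and Akt3. It also takes the 12 largest changes in each direction among passing genes with a mean of at least 5 CPM in the higher group in which every library of each group lay beyond the other group's median. Predicted genes, pseudogenes, Y-linked genes, Xist and receptor segments were left out. From each list it takes the up to 4 members with the smallest p. Where under 5 genes passed, it takes the 10 genes with the smallest p. The groups, comparisons, lists, naming rule and the first set of alternative settings were fixed before the data were examined. Among the genes the rule gives, those printed are a part.

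A background level was measured in each library, a step chosen after seeing the data. It is the count per kilobase of merged exon over 1134 protein-coding olfactory receptor genes (3659.6 kb), a family taken here as a measure of background, though single members can be expressed. Multiplied by exon length, it gives an expected background for every gene. A gene counts as "over background" where it is protein-coding and its mean over the libraries is at least 3 times that expectation, which holds for 7094 genes, 6951 of them tested. In a single library, a gene is over background where its count is at least 3 times the expected one and at least 10. For a group with no count of a gene, 3 counts over the group's libraries give the bound on its fold change. The bounds cover counting error only, since the reads carry no molecular identifiers.

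The first set of alternative settings was DESeq2 1.42.0, RLE factors, no filter, a filter of 1 CPM in 4 libraries (which kept more genes than the one used), limma-voom with quality weights, only the groups compared, the day of sacrifice as a covariate, keratinocyte and muscle scores as covariates, and leaving out each library in turn. Those added after seeing the data were subtraction of the background (list tests at both correlations), a test of only the genes over background, the log2 background as a covariate, leaving out the 5 libraries whose background exceeded 50%, using only the 17 libraries above 1% or the 5 below it, and thinning every library to the smallest total. Effects that share the Pten_null libraries were compared by correlation across genes, by simulated groups and by splitting those libraries. Each score is the mean log2 CPM of its marker list, without subtraction of background. No tested keratinocyte marker was over background, so that score can follow background. A value or list direction said to have turned changed sign against a passing main result, whatever its p in that setting.

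The fit was tested on simulated data with the measured dispersions and group sizes, 200 genes changed at random. For AKT1_E17K against Pten_null it recovered 2% of genes changed 2-fold, 34% at 4-fold, 74% at 8-fold and 92% at 16-fold. For Pten_null against Cdkn2a_null the shares were 2%, 32%, 58% and 88%.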

Results

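Gene expression was measured by RNA sequencing in 22 primary mouse melanomas that express BRAF V600E, a mutant kinase that drives the MAPK pathway, and, as labelled, lack Cdkn2a, which encodes the cell cycle inhibitors p16 and p19. There were 5 Cdkn2a_null tumours and 5 Pten_null tumours, labelled as also lacking Pten, the phosphatase that opposes PI3K. AKT1_E17K, AKT2_E17K and AKT3_E17K had 4 tumours each, with an activated mutant of 1 AKT kinase added to the Pten_null genotype. The comparisons ask what Pten loss changes in these tumours, what each mutant AKT changes beyond it, and whether the 3 mutant kinases differ.

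Library totals ran from 523052 to 9782192 counts. The mean was 8159730 ± 2572220 counts (SD, n = 4) in AKT1_E17K, 3482910 ± 3825690 (SD, n = 4) in AKT2_E17K, 1777220 ± 911178 (SD, n = 5) in Cdkn2a_null, 1036560 ± 405230 (SD, n = 5) in Pten_null and 908736 ± 244952 (SD, n = 4) in AKT3_E17K. The AKT2_E17K mean rests on replicate 4, with 9151896 counts, against 1005213 to 2406400 in the other 3. The group totals of AKT1_E17K and Pten_null did not overlap (exact permutation p = 0.00794, two-sided, the smallest this design can give; 0.111 after Benjamini-Hochberg over 70 tests of library measures).

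Counts also lay on genes that are silent in most tissues. Olfactory receptor genes, used as a measure of background, held as many counts per kilobase as would make up 11.4% to 69.5% of the protein-coding counts in 15 libraries, and 4.90% and 6.75% in Cdkn2a_null replicates 1 and 5. In the remaining 5 libraries, the 4 of AKT1_E17K and AKT2_E17K replicate 4, that share was 0.141% to 0.732%. The group mean was 33.3 ± 28.5% (SD, n = 5) in Cdkn2a_null, 43.3 ± 21.6% (SD, n = 5) in Pten_null, 0.318 ± 0.278% (SD, n = 4) in AKT1_E17K, 14.4 ± 11.6% (SD, n = 4) in AKT2_E17K and 38.81 ± 19.97% (SD, n = 4) in AKT3_E17K. AKT1_E17K lay below every Pten_null library (exact permutation p = 0.0159, two-sided, adjusted 0.111 over 70 tests). The 5 low libraries had counts in 20745 to 24456 genes, and the other 17 in 31451 to 37365 genes. Satellite-like genes took up to 63.3% of the counts of a library and ribosomal RNA-like genes up to 72.9%.

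The first principal component of log2 CPM held 66.8% of the variance. Over the 17 libraries above 1% background it followed log2 background, with Pearson's r = 0.993 and Spearman's rho = 0.971 (permutation p = 1e-05 for each, the smallest that 100000 permutations can give), and r = 0.986 without the 2 farthest libraries. These 17 hold no AKT1_E17K library.

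**Figure D1:**
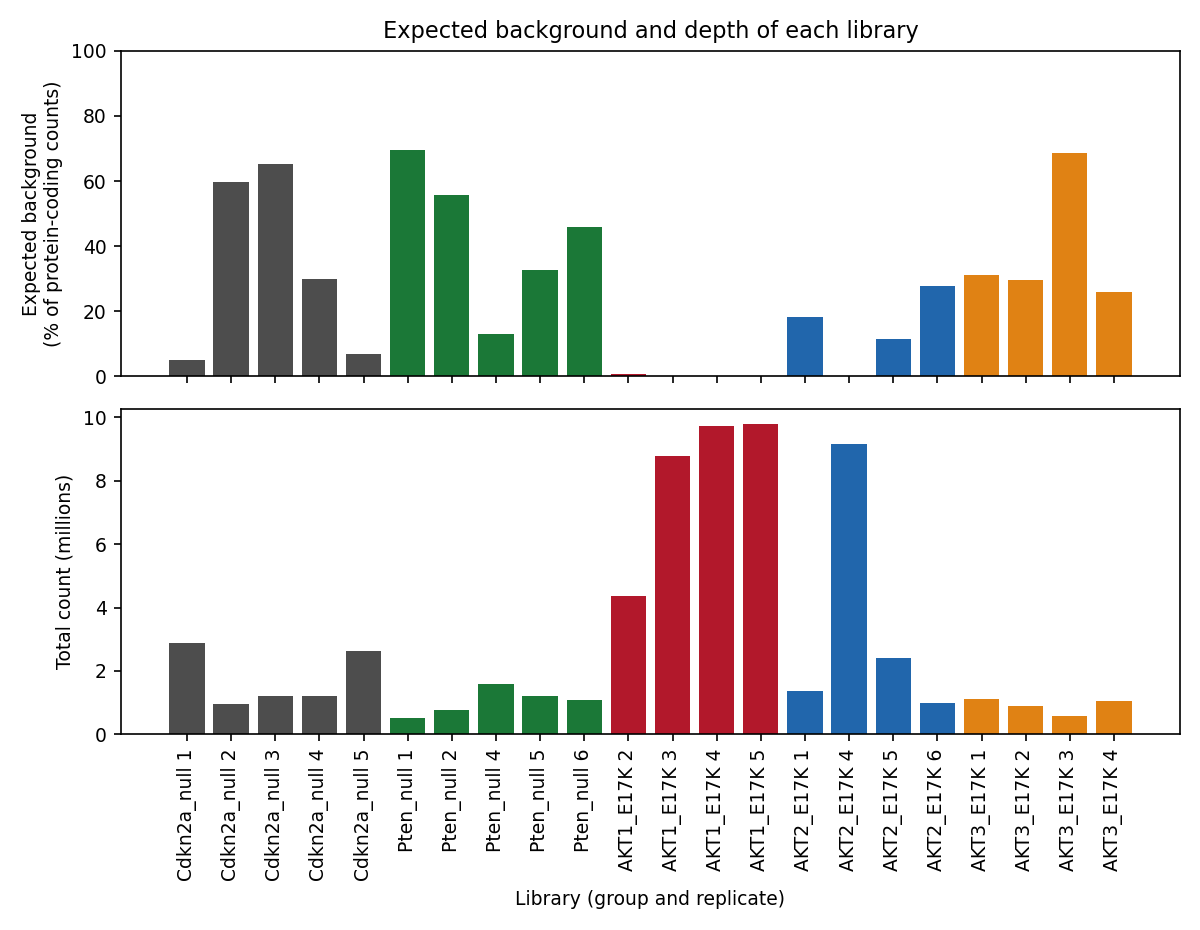
Expected background as a percentage of protein-coding counts (top) and total count (bottom), with 1 bar per library and 1 colour per group. Background is under 1% in the 4 AKT1_E17K libraries and AKT2_E17K replicate 4, and 4.90% to 69.5% in the other 17.

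The genes that the genotypes name were compared first. Pten (ENSMUSG00000013663, chromosome 19, 32757497 to 32826160, mm10) averaged 90.9 ± 47.3 CPM (SD, n = 5) in Pten_null and 109.5 ± 66.6 CPM (SD, n = 5) in Cdkn2a_null, a log2 fold change of -0.27 ± 0.51 (SE, adjusted p = 0.917). It averaged 197.4 ± 45.5 CPM (SD, n = 4) in AKT1_E17K, 222.6 ± 160.9 CPM (SD, n = 4) in AKT2_E17K and 79.5 ± 26.2 CPM (SD, n = 4) in AKT3_E17K, all on the Pten_null genotype. For AKT1_E17K against Pten_null, Pten had a log2 fold change of 1.11 ± 0.54 (adjusted p = 0.0833 in edgeR), 0.99 in DESeq2 (adjusted p = 0.0452) and 1.38 in limma-voom (adjusted p = 0.0313), but 0.21 with background subtracted (adjusted p = 0.866) and -1.03 with log2 background as a covariate. For AKT2_E17K it was 1.29 ± 0.54 (adjusted p = 0.334). A gene-level count includes exons outside a deletion and reads from cells other than tumour cells. A delivered transgene of another species or codon use need not map to the mouse gene. The Akt1, Akt2 and Akt3 counts below thus do not show whether a mutant kinase was expressed. Akt1 (ENSMUSG00000001729, chromosome 12, 112653821 to 112674884) averaged 233.3 ± 68.8 CPM (SD, n = 4) in AKT1_E17K and 69.4 ± 59.1 CPM in Pten_null, a log2 fold change of 1.73 ± 0.66 (adjusted p = 0.0339). That value turned to -1.08 with log2 background as a covariate, and all tested genes over background had a median of 0.98 in this comparison. Akt2 (ENSMUSG00000004056, chromosome 7, 27591552 to 27640826) averaged 65.0 ± 61.5 CPM in AKT2_E17K and 36.5 ± 7.68 CPM in Pten_null (log2 fold change 0.83 ± 0.38, adjusted p = 0.335). A single library, AKT2_E17K replicate 5, held 157.2 CPM of Akt2, and the other 3 held 31.9 to 36.6 CPM. Akt3 (ENSMUSG00000019699, chromosome 1, 177020073 to 177258203) averaged 54.8 ± 24.1 CPM in AKT3_E17K and 58.5 ± 37.8 CPM in Pten_null (log2 fold change -0.11 ± 0.55, adjusted p = 1). Its means were larger in the groups with another mutant kinase, at 118 ± 63.2 CPM in AKT1_E17K (log2 fold change against Pten_null 0.99 ± 0.54, adjusted p = 0.119) and 118.5 ± 44.9 CPM in AKT2_E17K (1.001 ± 0.539, adjusted p = 0.346). Braf (ENSMUSG00000002413, chromosome 6, 39603237 to 39725463) had group means between 52.3 and 73.8 CPM, and passed in none of the 4 tests against Pten_null or between Pten_null and Cdkn2a_null. Cdkn2a (ENSMUSG00000044303, chromosome 4, 89274471 to 89294653) did not pass the filter on low counts. It still had 24, 68, 88 and 77 counts in the AKT1_E17K libraries, against an expected background of 0.137 to 0.186. AKT2_E17K replicate 4 had 41 (0.179 expected), and Cdkn2a_null replicates 1 and 5 had 16 and 30 (1.05 and 1.11 expected). The other libraries had 0 to 11 counts, against 1.41 to 2.66 expected. The limit on gene-level counts given for Pten applies here too.

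Pten_null was compared with Cdkn2a_null for the effect of Pten loss. Sox10 and Plp1 were among the 10 named genes with the smallest p, none of which passed in edgeR. Sox10 (ENSMUSG00000033006), the transcription factor of neural crest, glia and melanocytes, averaged 54.6 ± 37.3 CPM (SD, n = 5) in Pten_null and 2.71 ± 1.69 CPM (SD, n = 5) in Cdkn2a_null, a log2 fold change of 4.56 ± 1.10 (SE). It stood over background in 4 of 5 Pten_null libraries and in 0 of 5 Cdkn2a_null libraries. Plp1, a myelin protein, averaged 213.0 ± 114.0 CPM against 18.4 ± 15.6 CPM (log2 fold change 3.60 ± 0.99), over background in 5 of 5 and 2 of 5 libraries. Both had an adjusted p of 0.905 in edgeR, so neither passed.

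The same held for the other genes with the smallest p in this comparison. The metalloproteinase gene Mmp15 had a log2 fold change of 3.96 ± 0.88, the collagen gene Col20a1 4.40 ± 1.21, the G protein-coupled receptor gene Gpr17 3.43 ± 0.86 and the glial calcium-binding protein gene S100b 3.24 ± 0.92. Values for Cadm4, a cell adhesion gene of myelinating glia, Moxd1 and Syt4 were 3.08 ± 0.88, 2.74 ± 0.76 and 2.57 ± 0.73. Erbb3, the neuregulin receptor gene, had 2.94 ± 0.87, and was the 1 of 19 tested FOXO targets that was higher adjusted over the list alone. Only Acta1 (ENSMUSG00000031972, skeletal muscle actin) had a lower mean in Pten_null, at 4.26 ± 2.49 CPM against 255.8 ± 368.1 CPM. The SD of Acta1 exceeds its mean in Cdkn2a_null. All are over background, at 4.74 to 44.8 times its expected level across libraries, and the 2 groups' background percentages overlapped (exact permutation p = 0.540, two-sided). AKT1_E17K and AKT2_E17K tumours also had Sox10 over background, in 4 of 4 and 3 of 4 libraries, while 1 of 4 AKT3_E17K libraries had it.

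**Figure D2:**
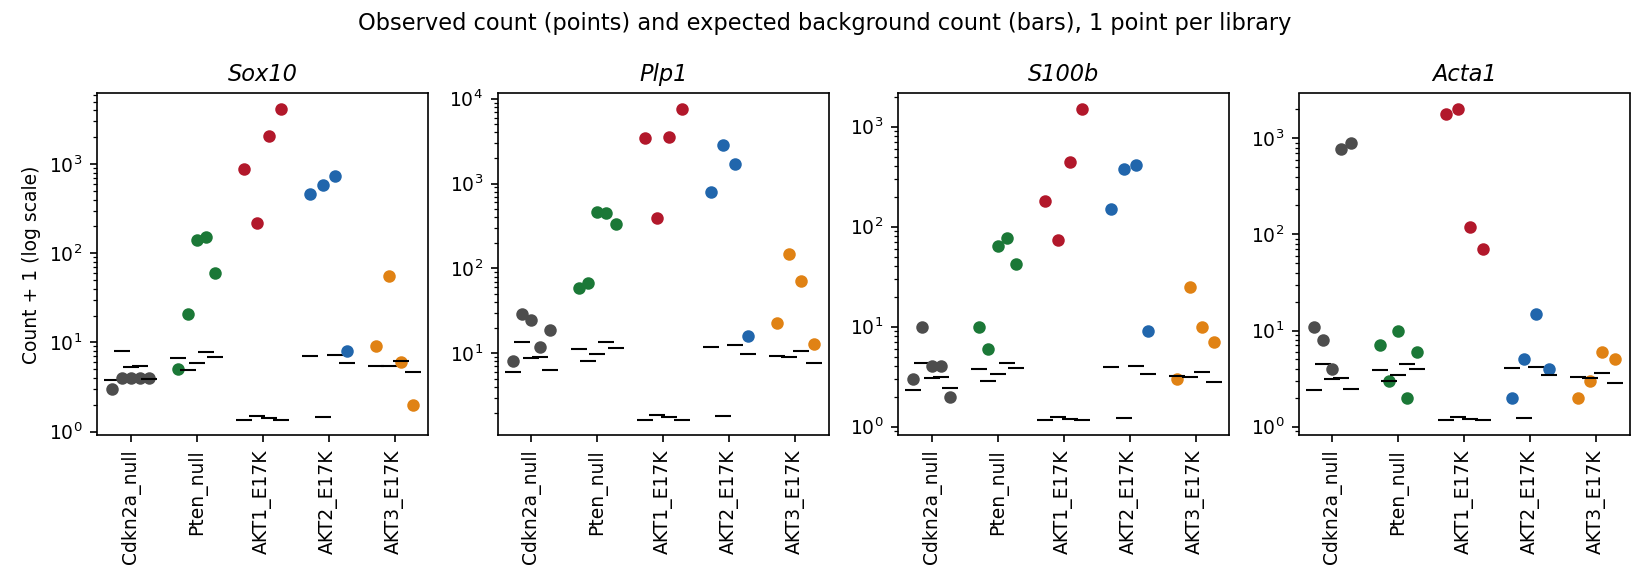
Counts plus 1 of Sox10, Plp1, S100b and Acta1 in each library on a log axis, 1 panel per gene, with points for the libraries of the 5 groups and bars for the background expected in each. Sox10 exceeds the bar at least 3-fold in 4 of 5 Pten_null and 0 of 5 Cdkn2a_null libraries, and Acta1 is concentrated in single libraries.

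By list, 1 of the 13 tested members of melanocyte pigmentation (Sox10) had a higher level in Pten_null when adjusted over the list alone, and 0 over all genes. The list moved up in camera (adjusted p = 0.00365), but adjusted p = 0.4998 with an estimated correlation, and only 2 of its 13 members, Sox10 and Ednrb, were over background. With background subtracted these 2 had a median of 6.91 (adjusted p = 0.000136, 0.0491 with an estimated correlation), and 0 passed. Sox10 then had a level of 0 in every Cdkn2a_null library, so this median depends on how an empty group is treated. It gives no size of the change and rests on 2 genes, not on the list. Schwann cell and nerve markers had 1 higher member adjusted over the list alone (Plp1) and 0 over all genes; Pmp22 and Cnp had log2 fold changes of 1.68 ± 0.75 and 1.36 ± 0.60. Camera gave an adjusted p of 0.0150, and adjusted p = 0.4998 with an estimated correlation. With background subtracted the 5 tested had a median of 2.28 (adjusted p = 0.0158, 0.0672 with an estimated correlation), and 0 passed. The list of neural crest and dedifferentiated melanoma did not move up: 0 of its 20 tested members passed, over all genes or adjusted over the list alone, and its median was -0.58 (camera adjusted p = 0.0910, 0.657 with an estimated correlation).

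The 6 lists that moved down in Pten_null with the smallest camera p were skeletal muscle, macrophage, antigen presentation, interferon response, MYC and ribosome biogenesis and oxidative phosphorylation. Of 16 skeletal muscle markers, 11 were lower adjusted over the list alone and 0 over all genes, with Tnnt3 at -4.48 ± 1.36, Atp2a1 at -4.16 ± 1.38 and Myh4 at -4.81 ± 1.65 log2. Their counts came from Cdkn2a_null replicates 4 and 5, which held 1629 and 654.6 CPM of Acta1 over background. The macrophage median was -1.26, with Csf1r, the receptor of the macrophage growth factor, at -1.44 ± 0.51, Fcer1g at -1.94 ± 0.70 and the complement gene C1qa at -1.53 ± 0.69. The antigen presentation median was -0.65, with the class II genes H2-Ab1 at -2.25 ± 0.81, H2-Aa at -2.05 ± 0.97 and Cd74 at -2.22 ± 1.08, and the interferon median was -0.65. MYC and ribosome biogenesis had a median of -0.41, with Odc1 at -1.72 ± 0.66, Ncl at -0.85 ± 0.40 and Myc at -1.05 ± 0.53, and oxidative phosphorylation had -0.63. In each of these 5 lists 0 members passed over all genes or adjusted over the list alone. Camera gave adjusted p values of 1.8e-06 for muscle, 2.4e-05 for macrophage, 7.6e-05 for antigen presentation, 0.000150 for interferon and 0.000135 for the last 2 lists. With an estimated correlation the adjusted p was 0.515 for oxidative phosphorylation and 0.4998 for the other 5. The median of all genes over background was -0.37, and -0.42 for the MYC and ribosome biogenesis members among them. With background subtracted, muscle had a median of -3.76 (camera adjusted p = 0.000438, 0.825 with an estimated correlation), while the other 5 lists had medians of -0.76 for macrophage (adjusted p = 0.0747), -0.33 for antigen presentation (0.102), -0.39 for interferon (0.468), -0.15 for MYC and ribosome biogenesis (0.164) and -0.29 for oxidative phosphorylation (0.164). MAPK output (median -0.57, camera adjusted p = 0.00865), focal adhesion and integrins (-0.50, 0.0129), p53 targets (-0.38, 0.0151) and extracellular matrix (-0.45, 0.0183) also moved down, with 0 members passing over all genes or adjusted over the list alone. With an estimated correlation the adjusted p was 0.657 for extracellular matrix and 0.635 for the other 3. With the keratinocyte and muscle scores as covariates, camera's direction turned up for antigen presentation (median 0.13), oxidative phosphorylation (0.12), extracellular matrix (0.56), focal adhesion (0.27) and p53 targets (-0.03).

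Over all 17686 genes, 0 passed in edgeR (smallest adjusted p = 0.905), with 555 at an unadjusted p under 0.05, 185 of them higher and 370 lower in Pten_null. These 555 are a smaller share of the genes than the 0.05 that uniform p values give. DESeq2 called 12 genes, among them Mmp15 (adjusted p = 0.000248), Sox10 (0.00109), Acta1 (0.00811), Plp1 (0.0120), Col20a1 (0.0159), Erbb3 (0.0385), Moxd1 (0.0385) and Cadm4 (0.0425). The other alternatives gave 0 in this comparison. On simulated libraries for this comparison, with 200 genes changed, DESeq2 called 14 unchanged genes and edgeR 2. DESeq2 also recovered more of the changed genes, 42% against 32% at 4-fold and 74% against 58% at 8-fold. The simulation does not tell how many of the 12 calls are false.

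AKT1_E17K was compared with Pten_null for the effect of mutant AKT1. Among 17686 genes, 3025 were higher and 6050 lower in AKT1_E17K. Of 6951 tested genes over background, 2636 were higher and 142 lower, with a median log2 fold change of 0.98, while the median of the genes not over background was -1.75. The normalization put the median of all genes at 0.01, so a fall in the genes near background raises the value of the others. A direction is relative to that point, and a list of genes over background is to be read against 0.98. The library background differed between the same groups, as given above, and this stands beside each gene group below. With the expected background subtracted, 123 genes passed, with log2 background as a covariate 15, and with the keratinocyte and muscle scores as covariates 1. Background in AKT1_E17K (0.141% to 0.732%) lay wholly below that in Pten_null (13.1% to 69.5%). A value with log2 background as a covariate thus rests on a slope assumed linear and equal in all groups. It cannot settle whether a gene or list changed, or in which direction.

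The largest increases among the genes the rule names were in short transcripts and muscle actin. Acta1 was 65.6-fold higher (log2 fold change 6.035 ± 1.555, SE, adjusted p = 0.00291), with 274.1 ± 413.0 CPM (SD, n = 4) in AKT1_E17K against 4.26 ± 2.49 CPM (SD, n = 5). Rmrp, an RNA of ribosomal RNA processing, was 52.5-fold higher (5.71 ± 1.44, adjusted p = 0.00241), and the small RNAs Scarna6, Snora73b and Rny1 rose by 4.46 ± 1.05, 4.06 ± 1.14 and 3.65 ± 1.13 log2. The background criterion covers protein-coding genes only and so leaves these 4 RNAs out. With log2 background as a covariate Scarna6, Snora73b and Rny1 turned to -0.395, -0.894 and -1.135. With the keratinocyte and muscle scores they turned to -0.932, -1.587 and -2.476, while Rmrp turned in neither. Of the 12 genes named for the largest increases 4 were histone genes, for which no list was tested. Hist2h2bb was at 4.57 ± 0.99, Hist1h4c at 3.94 ± 0.98, Hist1h2ak at 3.73 ± 0.83 and Hist1h2bg at 3.71 ± 0.77. The copper chaperone gene Atox1, the respiratory chain gene Cox7b and the ribosomal protein gene Rps27l rose by 3.65 ± 0.90, 3.55 ± 0.68 and 3.54 ± 0.86. Of these, Atox1 turned to -0.69 with log2 background as a covariate. Hist2h2bb and Cox7b also passed with the background subtracted (log2 fold changes 3.62 and 3.10, adjusted p = 0.0430 for both).

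The largest decreases among named genes were in genes with no or almost no count in AKT1_E17K. Cacna2d4, a calcium channel subunit gene of the retina, was at least 458-fold lower, with 0 counts in 4 libraries against 40.1 ± 15.1 CPM in Pten_null. Ros1, Six3os1, Otof, Cntnap2, Fer1l4, Fam155a and Abca17 were at least 201-fold to 266-fold lower, each at 1.04 to 1.76 times the expected background across libraries. Ush2a fell by 8.92 ± 1.21 log2, at 1.25 times background. Smok2a, Btnl4 and Duxf3, at least 274-fold, 203-fold and 214-fold lower, were over background, at 3.04 to 7.71 times, and passed with the background subtracted (adjusted p = 0.00877 for each). A gene with denser background than the measured one would also pass there, so this does not show a change in expression. Duxf3 is a member of the tandemly repeated Dux array.

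Energy metabolism and biosynthesis lists held more higher than lower members in AKT1_E17K. So did all tested genes over background, with 2636 of 6951 higher and 142 lower, and the counts below are to be read against that. Of 20 tested oxidative phosphorylation genes, 15 were higher and 1 lower, and 17 and 1 adjusted over the list alone; Ndufv1, Cyc1 and Uqcrc2 rose by 1.64 ± 0.38, 1.59 ± 0.38 and 2.18 ± 0.54 log2. In sterol and fatty acid synthesis, 6 of 19 were higher and 0 lower, and 4 adjusted over the list alone, with Acly, Fasn, Ldlr and Srebf2 at 1.88 ± 0.48, 1.76 ± 0.60, 1.20 ± 0.37 and 1.58 ± 0.54. Glycolysis and hypoxia had 2 of 20 higher, Eno1 (2.30 ± 0.60) and Pkm (2.21 ± 0.87), and 1 adjusted over the list alone. In the amino acid response, 4 of 18 were higher and 1 lower, and 3 and 1 adjusted over the list alone; the transporter gene Slc7a5 rose by 1.78 ± 0.55, Psat1 by 1.24 ± 0.38 and Aldh18a1 by 1.22 ± 0.34. All higher members of these 4 lists were over background. Against the 0.98 of all genes over background, the medians of the members over background were 1.58 for oxidative phosphorylation, 1.07 for sterol and fatty acid synthesis, 0.59 for glycolysis and hypoxia and 1.22 for the amino acid response. With log2 background as a covariate camera's direction turned down in all 4, with medians of -0.37, -0.20, -1.26 and -0.57 in the same order. Glycolysis also turned with background subtracted (-0.27, camera adjusted p = 0.778), with genes over background only (-0.29) and with the keratinocyte and muscle scores as covariates (-0.75).

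Among passing members of the signalling and growth lists, more were higher than lower. The same held for all tested genes over background (2636 of 6951 higher, 142 lower), so this direction is not particular to these lists. Of 18 MAPK output genes, 7 were higher and 1 lower, and 7 and 1 adjusted over the list alone, with Epha2, Phlda1 and Etv4 at 1.89 ± 0.47, 1.72 ± 0.57 and 1.52 ± 0.57. Of 19 FOXO targets, which AKT is known to repress, 3 were higher and 1 lower, and 0 and 1 adjusted over the list alone; Irs2 and the insulin receptor gene Insr rose by 1.63 ± 0.58 and 1.25 ± 0.43. In MYC and ribosome biogenesis 9 of 18 were higher and 1 lower (12 and 1 adjusted over the list alone), with Gnl3 at 1.49 ± 0.46 and Bop1 at 1.35 ± 0.42. Cell cycle had 8 of 22 higher and 1 lower (5 and 1 adjusted over the list alone); Cdc20 and Ccnb2 rose by 2.28 ± 0.44 and 1.64 ± 0.54, and the replication factor Cdc6 fell by 1.44 ± 0.42. In p53 targets 9 of 18 were higher and 1 lower (10 and 1 adjusted over the list alone), with Ccng1 at 2.50 ± 0.80 and Phlda3 at 1.83 ± 0.61. Of the higher p53 targets 6 were over background, as were all higher members of the other 4 lists. The medians of the members over background were 1.52 for MAPK output, 0.84 for FOXO targets, 0.98 for MYC and ribosome biogenesis, 0.9954 for cell cycle and 1.15 for p53 targets. With log2 background as a covariate MAPK output (-0.70), FOXO targets (-0.63) and p53 targets (-0.42) turned down. FOXO targets also turned with the scores (-0.54) and with genes over background only (-0.07).

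In the adhesion and matrix lists the passing members were all higher, where 2636 of all 6951 tested genes over background were higher and 142 lower. Focal adhesion and integrins had 11 of 26 higher and 0 lower, 10 adjusted over the list alone, among them Ilk (2.18 ± 0.61), Tln1 (1.89 ± 0.62) and Bcar1 (1.38 ± 0.40). Extracellular matrix had 7 of 22 higher and 0 lower, 0 adjusted over the list alone, with the collagen genes Col6a1, Col5a2 and Col5a1 at 2 ± 0.63, 1.98 ± 0.72 and 1.74 ± 0.65. In neural crest and dedifferentiated melanoma, 5 of 20 were higher and 0 lower, 0 adjusted over the list alone; the matrix gene Tnc rose by 2.60 ± 0.78, Cdh2 by 1.75 ± 0.66 and Jun by 1.72 ± 0.68. Every higher member of these 3 lists was over background, and the medians of the members over background were 1.46, 1.76 and 1.48. All 3 turned down with log2 background as a covariate, to -0.60, -0.99 and -1.18, and extracellular matrix also with the scores (-1.10).

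Markers of other cell types moved in opposite directions. Skeletal muscle had 6 of 16 higher, 5 of them over background, and 3 adjusted over the list alone, with Atp2a1, Myh1 and Tnnt3 at 4.29 ± 1.41, 4.19 ± 1.24 and 3.64 ± 1.36. Limma-voom turned these 3 values to -0.93, -0.82 and -0.01. Macrophage markers had 2 of 15 higher, Lyz2 (2.55 ± 0.87) and Tyrobp (1.79 ± 0.66), fibroblast markers 2 of 11, Lum (2.30 ± 0.67) and Dcn (2.11 ± 0.73), and antigen presentation 1 of 15, H2-Ab1 (2.11 ± 0.83); adjusted over the list alone these counts were 0, 2 and 0. Camera's direction turned down for skeletal muscle in limma-voom (median -1.39). It also turned down for antigen presentation and macrophage with log2 background as a covariate (-1.27 and -0.27), with the scores (-1.40 and -0.47) and with background subtracted (-0.08 and 0.24). Both lists had a camera adjusted p of 0.961 with background subtracted, so neither passed there.

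Keratinocyte markers were lower in 10 of 10 tested, and 10 adjusted over the list alone, with none over background; Krt1 and Dsg3 were at least 114-fold and 163-fold lower, Flg had a log2 fold change of -5.84 ± 0.87 and Trp63 -6.04 ± 1.02. The keratinocyte median was -5.80, and -5.80 with the 3 genes that had no count in AKT1_E17K at their bounds. Hair follicle markers were lower in 3 of 3 (3 adjusted over the list alone), with Krt35 at least 110-fold lower, and a median of -4.94 that the bound left as it was. T and NK cell markers were lower in 9 of 10, 9 adjusted over the list alone, with Cd3e falling by 5.13 ± 0.82 and Cd8a by 4.66 ± 0.69, and 2 of the 9 were over background. With background subtracted, 3 of 3 tested T and NK cell genes were lower, with a median of -4.61 (camera adjusted p = 1.9e-05, 0.110 with an estimated correlation). The limit of the subtraction given for Smok2a applies to these genes too. B and plasma cell markers were lower in 5 of 6 (5 adjusted over the list alone), with Cd19 and Pax5 at -6.39 ± 0.89 and -5.58 ± 0.91. The B and plasma cell list and the hair follicle list had too few members over background to be tested with background subtracted. Pigmentation had 1 of 13 higher and 9 lower, 2 and 9 adjusted over the list alone, with Trpm1 at -8.03 ± 1.11, a median of -3.46 with or without its 1 empty gene at its bound, and none of the 9 over background. The 2 members over background had a median of 1.98, and camera's direction turned up with background subtracted (median 0.90, adjusted p = 0.822) and with genes over background only (1.08). That of B and plasma cells turned up with log2 background as a covariate (median 0.94).

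The remaining lists had few passing members. Interferon response had 5 of 19 lower (5 adjusted over the list alone), with Cxcl9 at -2.62 ± 0.51 and Mx1 at -2.33 ± 0.54; neutrophil markers had 2 of 5 lower (3), with Ltf at -3.97 ± 0.81. Endothelial markers had 1 of 12 higher and 4 lower (1 and 4 adjusted over the list alone), with Vwf at -1.67 ± 0.38. Pericyte and smooth muscle markers had 2 of 10 lower (2), with Lmod1 at -4.74 ± 1.10. Adipocyte markers had 1 of 7 higher and 4 lower (1 and 4), with the leptin gene Lep at -5.52 ± 1.04, and Schwann cell and nerve markers had 3 of 10 lower (3), with Mag at -4.20 ± 0.80. The Schwann cell median was 0.21, while its mean was -0.58 and camera's direction was down. Red blood cell markers had 2 of 3 lower (2), with Slc4a1 at -5.53 ± 0.92 and the haemoglobin gene Hbb-bs at 0.22 ± 0.98, which did not pass. All lower members of these 7 lists lay within 3 times the background. With background subtracted, interferon response had a median of -1.31 over 9 tested genes, with 0 passing (camera adjusted p = 0.00103, 0.387 with an estimated correlation). Without the subtraction these 9 had a median of -0.14, and the list an adjusted p of 0.461.

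In camera, 20 of the 28 lists had an adjusted p under 0.05 for AKT1_E17K against Pten_null, and 0 with an estimated correlation, where the smallest adjusted p was 0.458. Of the 53 higher genes given here by name, 2 of the 48 that could be tested passed with background subtracted and 0 of 53 with log2 background as a covariate, where 25 of the 53 turned direction. DESeq2, run without edgeR's filter on low counts, called 25839 genes.

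**Figure D3:**
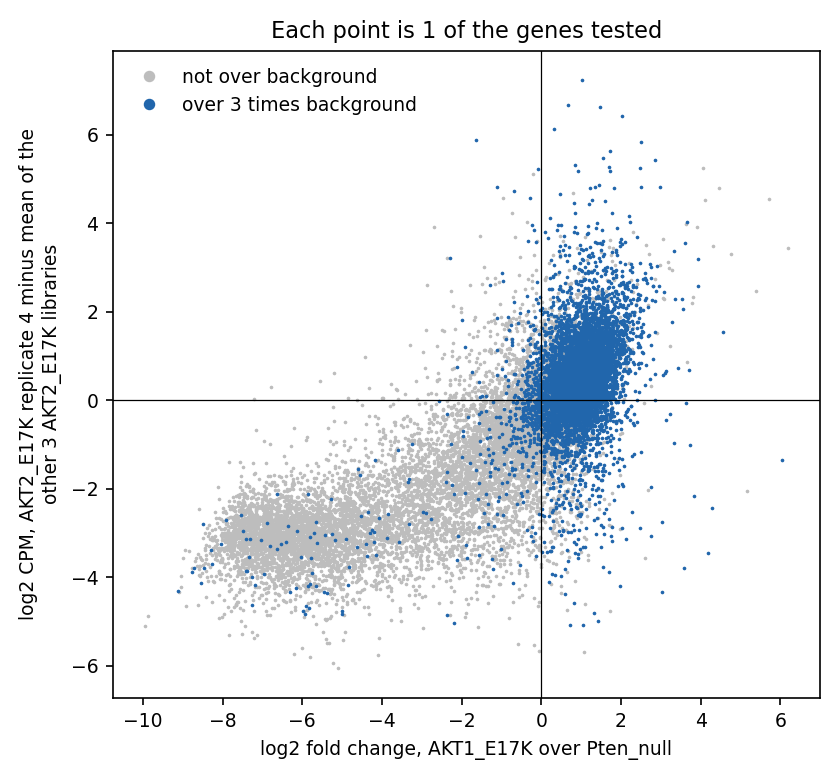
Each point is 1 gene over background or not, as coloured, with its log2 fold change between AKT1_E17K and Pten_null on the x axis and its log2 difference between AKT2_E17K replicate 4 and the other 3 AKT2_E17K libraries on the y axis. Of the 9075 genes that passed, 92.9% lie on the same side of 0 on both axes, with 97.3% of the lower and 84.1% of the higher ones.

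AKT2_E17K was compared with Pten_null for the effect of mutant AKT2. The AKT2_E17K tumours were taken later, on day 49 to 88 against 36 to 53 in Pten_null. The exact permutation p was 0.0317 (two-sided, adjusted 0.117 over 70 tests). The secreted protease gene Htra1 had the smallest p, with 224.0 ± 186.1 CPM (SD, n = 4) in AKT2_E17K and 17.8 ± 6.27 CPM (SD, n = 5) in Pten_null, a log2 fold change of 3.64 ± 0.74 (SE). Next came the glycogenin gene Gyg (1.73 ± 0.36), the respiratory chain genes Cox7b (3.24 ± 0.68) and Uqcr11 (2.51 ± 0.58), Cd302 (2.77 ± 0.61), the ceruloplasmin gene Cp (2.95 ± 0.68) and the cobalamin transporter gene Tcn2 (2.01 ± 0.48). Zfp800, Emp2 and the small RNA Rny3 had 1.29 ± 0.30, 1.83 ± 0.43 and 3.31 ± 0.78. The adjusted p was 0.334 for each, so none passed; Zfp800 and Emp2 were not over background.

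In the lists, 0 members passed over all genes. Camera's lowest adjusted p values were for focal adhesion and integrins (9.7e-05, median 0.94), oxidative phosphorylation (0.000141, median 1.03), glycolysis and hypoxia (0.000170, median 1.15), extracellular matrix (0.000282, median 1.32) and neural crest and dedifferentiated melanoma (0.00313, median 1.05). With an estimated correlation each had an adjusted p of 0.569. The median of all genes over background was 0.66 here, and the members over background had 1.04, 1.05, 1.25, 1.32 and 1.02, in the same order. With background subtracted, the 5 medians were 0.45 (adjusted p = 0.0449), 0.39 (0.176), 0.63 (0.176), 0.66 (0.273) and 0.48 (0.273), and the first had adjusted p = 0.977 with an estimated correlation. With log2 background as a covariate camera's direction turned down for extracellular matrix (median 0.45). Their members with small p included Itgav (1.57 ± 0.64) and Ilk (1.39 ± 0.61), Uqcrc2 (1.72 ± 0.54) and Sdhb (1.10 ± 0.44), the hypoxia genes Adm (2.62 ± 1.06), Egln3 (1.64 ± 0.69) and Bnip3 (1.83 ± 0.83), Fn1 (2.47 ± 1.10), Col12a1 (1.87 ± 0.81) and Timp1 (2.56 ± 1.14), and Serpine1 (2.08 ± 0.64) and Thbs1 (3.46 ± 1.25). Adjusted over the list alone, 0 members of these 5 lists passed. In pigmentation, 1 of 13 was higher adjusted over the list alone, the melanocyte regulator Mitf at 1.28 ± 0.36 log2, which was not over background. Skeletal muscle had a median of -1.09, an adjusted p of 0.0227, 0 members adjusted over the list alone, and adjusted p = 0.715 with an estimated correlation. With background subtracted, muscle had a median of -1.96 (adjusted p = 9e-05, 0.977 with an estimated correlation) and T and NK cell genes, 3 tested, -2.40 (adjusted p = 0.00406, 0.638 with an estimated correlation). Over all genes, 0 passed in edgeR, with 2618 at an unadjusted p under 0.05 (1980 higher, 638 lower) and 2 called by DESeq2, 1 of them Htra1 (adjusted p = 0.00830). Without AKT2_E17K replicate 1, edgeR called 2, 1 of them Htra1 (adjusted p = 0.00477).

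AKT3_E17K was compared with Pten_null for the effect of mutant AKT3, and the fewest genes had a small unadjusted p here. The gene with the smallest p was Thbs4, a matrix protein gene, at 286.5 ± 533.6 CPM (SD, n = 4) in AKT3_E17K and 15.8 ± 14 CPM (SD, n = 5) in Pten_null; its mean rests on AKT3_E17K replicate 4, with 1087 CPM. The matrix gene Fmod had 4.44 ± 1.49 log2 and Chodl 2.741 ± 1.003. Negative values were those of Panx1 (-0.89 ± 0.27), Tipin (-1.02 ± 0.32), Myef2 (-2.44 ± 0.77), Slitrk2 (-2.30 ± 0.74), Tmem29 (-0.85 ± 0.30), Ndufa1 (-1.77 ± 0.63) and B4galt6 (-1.96 ± 0.71). Each had an adjusted p of 1. Panx1, Slitrk2, Tmem29 and Chodl were not over background.

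Extracellular matrix had a median of 0.56 and an adjusted p of 0.00242 in camera, with Fn1 at 1.503 ± 1.071 and Lox at 1.17 ± 0.77. Without AKT3_E17K replicate 4 the matrix median was -0.25, and without Pten_null replicate 4 it was 1.20. Sterol and fatty acid synthesis had a median of -0.38 and an adjusted p of 0.00849. Both had adjusted p = 0.9826 with an estimated correlation, and 0 members of either list passed, over all genes or adjusted over the list alone. Over all genes 0 passed in edgeR (smallest adjusted p = 1), with 87 at an unadjusted p under 0.05, and 0 in DESeq2. These 87 are a smaller share of the 17686 tested genes than the 0.05 that uniform p values give. The small count thus does not show that the groups are alike. Simulated changes of 16-fold were recovered in 76% of genes at these group sizes, and 2-fold changes in 2%. At the same depths with a dispersion of 0.05 these shares were 94% and 40%.

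AKT1_E17K was compared with AKT2_E17K to ask whether these kinases differ. The day of sacrifice was 34 to 48 in AKT1_E17K and 49 to 88 in AKT2_E17K, without overlap. Its exact permutation p was 0.0286 (two-sided, adjusted 0.111 over 70 tests), the smallest this design can give. An effect of the day thus cannot be told apart from the kinases. With the day as a covariate, 5 of the 13 higher genes named here and 8 of the 9 lower ones named here and below still passed. Higher in AKT1_E17K were the muscle genes Acta1 (log2 fold change 6.99 ± 1.77, adjusted p = 0.003855), Fhl1 (3.44 ± 0.96, adjusted p = 0.00829) and Myl9 (3.36 ± 0.78, adjusted p = 0.00196), and the matrix genes Col1a1 (2.99 ± 1.08, adjusted p = 0.0427) and Sned1 (2.62 ± 0.76, adjusted p = 0.0108). Acta2, Hist1h4a, Hic1 and the immediate early gene Ier2 rose by 2.03 ± 0.64, 1.99 ± 0.74, 1.61 ± 0.57 and 1.56 ± 0.46. Of 16 skeletal muscle markers, 11 were higher, and 15 adjusted over the list alone, with Myh1 at 5.25 ± 1.43 and Mb at 4.58 ± 1.31; camera gave 8.4e-06, and adjusted p = 0.424 with an estimated correlation. AKT1_E17K replicates 2 and 3 held 1153 and 292.5 CPM of Acta1 over background. Cell cycle had 1 of 22 higher, Cdc20 (1.41 ± 0.44), and 0 adjusted over the list alone; Cdk1 had 1.27 ± 0.54 and did not pass. Camera gave the list 7.9e-07, and adjusted p = 0.424 with an estimated correlation. Pericyte and smooth muscle markers had 2 higher, Acta2 and Tagln (1.75 ± 0.64), and 2 lower, with Lmod1 at -3.74 ± 1.10, and 2 and 3 adjusted over the list alone. Sned1 turned to -0.059 with the keratinocyte and muscle scores, Myh1 to -0.029 in limma-voom, and Lmod1 to 1.045 with log2 background as a covariate.

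Most passing genes were lower, 4616 against 88 higher over all genes, and 102 against 54 of those over background. Cacna2d4 and Smok2a, with 0 counts in AKT1_E17K, were at least 196-fold and 135-fold lower, and Ush2a fell by 8.03 ± 1.21 log2; of the 3 only Smok2a was over background. Pigmentation had 10 of 13 lower (11 adjusted over the list alone), with Trpm1 at -7.03 ± 1.10, keratinocyte markers 8 of 10 (10), with Flg at -4.78 ± 0.86, and B and plasma cell markers 5 of 6 (5), with Cd19 at -5.32 ± 0.88. T and NK cell markers had 8 of 10 lower (8 adjusted over the list alone), with Cd8a at -3.38 ± 0.69, and interferon response 5 of 19 (5), with Mx1 at -1.86 ± 0.54. Of the lower members of these 5 lists, 2 T and NK cell genes were over background. With background subtracted, 0 members of the last 2 lists passed, with medians of -1.85 over 3 T and NK cell genes (camera adjusted p = 0.00503) and -0.74 over 9 interferon genes (0.000744), and 0.286 for both with an estimated correlation. Camera's direction turned up for pigmentation with background subtracted (median 0.46, adjusted p = 0.504) and with genes over background only (0.4958). With log2 background as a covariate it turned up for B and plasma cells (0.96) and for T and NK cells (-0.22). The count over all genes was 0 with only these groups in the fit and 0 with background subtracted.

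AKT1_E17K was also compared with AKT3_E17K. Genes higher in AKT1_E17K included Acta1 (log2 fold change 6.27 ± 1.75), Col20a1 (4.28 ± 1.31), Kank4 (4.26 ± 1.12), Mmp15 (4.10 ± 0.95), Hist1h2bg (4.47 ± 0.94), Hist2h2bb (4.42 ± 1.10) and Hist2h2ac (4.39 ± 1.12), with adjusted p values from 0.000503 to 0.0112. Sterol and fatty acid synthesis had 11 of 19 higher and 0 lower, and 11 adjusted over the list alone, with Acly, Srebf1 and Fasn at 1.84 ± 0.52, 2.11 ± 0.65 and 2.15 ± 0.66; 8 of the 11 were over background. The 13 members over background had a median of 1.37, where all genes over background had 0.91. Camera gave 0.000463, and adjusted p = 0.497 with an estimated correlation. The 3 values turned to -0.34, -0.95 and -0.47 with log2 background as a covariate. Schwann cell and nerve markers had 3 of 10 higher, among them Cnp (2.86 ± 0.70), and 3 lower, and the same counts adjusted over the list alone. Pigmentation had 2 of 13 higher and 9 lower, 2 and 10 adjusted over the list alone, with Trpm1 at -7.89 ± 1.12 and none of the 9 over background. The median was -2.57 with or without its empty gene at the bound, but 3.06 for the 2 members over background. Camera's direction for pigmentation turned up with background subtracted (median 2.34, adjusted p = 0.125). T and NK cell markers had 9 of 10 lower (9 adjusted over the list alone), 2 of them over background. With background subtracted 1 of 3 was lower, with a median of -4.26 (camera adjusted p = 3.7e-05, 0.135 with an estimated correlation). Interferon response had 9 of 19 lower (9 adjusted over the list alone), 3 of them over background. With background subtracted 0 of 9 passed, with a median of -0.79 (adjusted p = 0.000225, 0.285 with an estimated correlation). Oxidative phosphorylation had 12 of 20 higher and 1 lower, and 13 and 2 adjusted over the list alone; its median was 0.57 with background subtracted (adjusted p = 0.0181, 0.770 with an estimated correlation), and it turned down with log2 background as a covariate (-0.61). For the sterol list that adjusted p was 0.102. Over all genes, 2226 were higher and 5827 lower, with 1866 higher and 138 lower over background. With background subtracted 85 passed, and 82 with log2 background as a covariate.

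AKT2_E17K and AKT3_E17K, both with background in most libraries, gave 0 passing genes in edgeR, with 1902 at an unadjusted p under 0.05 (1407 higher, 495 lower). The smallest p values belonged to Tcn2 (2.65 ± 0.55), Rny3 (4.03 ± 0.91), Htra1 (3.56 ± 0.81), Hsd17b11 (1.89 ± 0.44), Comt (1.71 ± 0.41), Cox7b (3.10 ± 0.75), Ndufa1 (2.53 ± 0.62), the myelin gene Cnp (2.80 ± 0.70), B4galt6 (2.96 ± 0.75) and the replication gene Tipin (1.27 ± 0.32), each with an adjusted p of 0.452. DESeq2 called 11, among them Htra1 and Rny3 (adjusted p = 0.00610), Cox7b, Cnp and B4galt6 (0.0444) and Pmp22 (0.0492). Schwann cell and nerve markers had 2 of 10 higher adjusted over the list alone and 0 over all genes, with Pmp22 at 3.09 ± 0.86, Cnp as above and Plp1 at 2.31 ± 1.03. Camera gave adjusted p values of 0.000190 for focal adhesion and integrins, with Itga2 at 2.38 ± 0.74 and Itgav at 1.91 ± 0.70, of 0.00164 for sterol and fatty acid synthesis, with Srebf1 at 1.66 ± 0.64 and Acly at 1.12 ± 0.51, and of 0.00146 for glycolysis and hypoxia, with Pgk1, not over background, at 1.74 ± 0.72. The members over background had medians of 1.02, 1.04 and 1.10, where all genes over background had 0.62, and with background subtracted the adjusted p was 0.0560, 0.122 and 0.301. Camera's direction for glycolysis turned down with log2 background as a covariate (median 0.04). With an estimated correlation the adjusted p was 0.716, 0.716 and 0.744, and 0 members of these 3 lists passed, over all genes or adjusted over the list alone.

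The mean of the 3 AKT groups was compared with Pten_null as an average, which can rest on 1 group. In edgeR, AKT2_E17K and AKT3_E17K each had 0 genes of their own against Pten_null, with 2618 and 87 at an unadjusted p under 0.05 (2 and 0 called by DESeq2). The mitochondrial genes mt-Cytb (log2 fold change 1.95 ± 0.59, adjusted p = 0.0179) and mt-Nd2 (1.78 ± 0.54, adjusted p = 0.0192) were higher, as were Lamtor5 and Rraga of the lysosomal amino acid sensing machinery (2.27 ± 0.65 and 1.68 ± 0.45), Rpl26 (2.07 ± 0.57), Fxyd5 (1.57 ± 0.50) and Cd24a (1.71 ± 0.58). Duxf3, S1pr5 and the olfactory receptor gene Olfr145 fell by 3.64 ± 0.68, 3.53 ± 0.57 and 3.50 ± 0.60. In all, 271 genes were higher and 4146 lower, with 223 and 86 over background. The count was 1 without the 5 libraries whose background exceeded 50%, and 1 with background subtracted. It was 0 with log2 background as a covariate and 0 with the keratinocyte and muscle scores. Leaving out 1 library gave 2637 (without Pten_null replicate 1) to 6447 (without Pten_null replicate 4). Any difference between the 5 groups passed for 6457 genes, 1266 of them over background, and for 0 with background subtracted.

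Effects of the 3 kinases against the shared Pten_null libraries were compared across 17019 genes, which are not independent replicates. AKT1_E17K and AKT2_E17K effects had a correlation across genes of 0.811 and a covariance of 2.19, where simulated groups without changes gave 0.482 and 0.182, and split Pten_null libraries gave 0.734 and 2.12. The simulation drew each gene independently, so its groups lack any background difference shared across genes. A value above or below the simulated one thus does not show a shared kinase effect or its absence. AKT1_E17K and AKT3_E17K effects had 0.121 and 0.138 (simulated 0.460 and 0.182), and AKT2_E17K and AKT3_E17K effects 0.258 and 0.0979 (simulated 0.453 and 0.183). With split Pten_null libraries the correlations with AKT3_E17K effects were 0.028 for AKT1_E17K (-0.597 to 0.502 over splits) and 0.048 for AKT2_E17K (-0.578 to 0.546). Leaving out 1 library gave -0.104 to 0.456 and 0.070 to 0.605, in the same order. In edgeR with all libraries only AKT1_E17K had calls, so none was shared; DESeq2, and edgeR without AKT2_E17K replicate 1, each called 2 genes for AKT2_E17K, and their overlap was not counted. The AKT1_E17K and AKT2_E17K libraries include the 5 with a background under 1%.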

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

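The tests of depth, of an effect of mutant AKT1, of background for the 9 genes higher in Pten_null and of adult muscle were chosen only after the result was seen; the other tests were chosen before it. Within groups of 4 or 5 libraries, 21 values lay far from the others among 140 groups of values tested, where chance gives about 1 in 20 groups (7).

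Single libraries stood apart in their overall composition. AKT1_E17K replicate 2 had the fewest genes with a count (20745, others 23827 to 24385), the highest background of its group (0.7321%, others 0.141% to 0.2225%) and the highest share of ribosomal RNA-like counts (40.82%, others 2.094% to 7.984%). AKT2_E17K replicate 4 had 24456 genes with a count (others 35214 to 37202). AKT3_E17K replicate 3 had a background of 68.59% (others 25.89% to 31.26%) and 34.98% ribosomal RNA-like counts (others 0.8935% to 2.218%).

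Single genes stood apart in others. AKT3_E17K replicate 2 was the highest of its group in 6 of the genes with the smallest p between Pten_null and Cdkn2a_null, at 56.02 CPM of Sox10, 44.61 of Mmp15, 26.97 of Gpr17, 195 of Col20a1, 51.87 of Moxd1 and 51.87 of Syt4. AKT2_E17K replicate 5 had 157.2 CPM of Akt2 and 133.3 CPM of Gpr17. AKT1_E17K replicate 3 was lowest in Mmp15 (59.33 CPM) and Myef2 (56.84 CPM), and AKT3_E17K replicate 3 in Htra1 (12.34 CPM). Thbs4 was highest in Pten_null replicate 4 (40.24 CPM) and AKT3_E17K replicate 4 (1087 CPM), and Col1a1 in Cdkn2a_null replicate 5 (3818 CPM) and AKT3_E17K replicate 4 (4986 CPM).

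The first pattern is the 9075 genes that differ between AKT1_E17K and Pten_null. Of these, 92.87% moved the same way between AKT2_E17K replicate 4, a low-background library, and the other 3 AKT2_E17K libraries, which share its genotype: 97.26% of the lower genes, 84.1% of the higher and 84.99% of those over background, where 80.22% of all tested genes did. Replicate 4 also had more counts, 9151896 against 1005213 to 2406400, and a later day of sacrifice, 88 against 49 to 58. The contrast rests on a single tumour and cannot assign the agreement to background rather than to depth, day or that tumour. A difference in background may account for much of the lower genes, and how much of the higher ones stays open. Depth alone is argued against, since 2273 genes passed with every library thinned to the smallest total; with background subtracted 123 genes passed, and 3 of 3 T and NK cell genes tested were lower (median -4.61), but every AKT1_E17K library has a low background and every Pten_null library a high one, so an effect of mutant AKT1 cannot be told apart from it. The count of 9075 was reached by 2 of 100 splits, the real one included, a share of 0.02. This share was not corrected over the comparisons, so chance is argued against but not excluded. The other split grouped Pten_null replicate 4 with AKT1_E17K libraries and gave 10094. A structure of the libraries other than their groups thus stays open.

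The second pattern is Sox10, Plp1 and 7 other genes of higher mean in Pten_null than in Cdkn2a_null, none of which passed in edgeR. Background as the whole cause is argued against: their median log2 fold change was 3.43 (range 2.57 to 4.56), and 3.407 with log2 background as a covariate. Peripheral nerve is argued against, since Mpz, an abundant myelin transcript of nerve, had 0.002683 of the counts of Plp1 in Pten_null. An effect of Pten loss stays open as an untested hypothesis, as does a difference in the cells sampled. Chance cannot be excluded for this comparison, with 555 genes at an unadjusted p under 0.05 and 6778 in the highest other split, which follows the background of the libraries (26 of 100 splits gave as many).

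The third pattern is skeletal muscle markers in single libraries of 2 groups. In the libraries with Acta1 at 100 CPM or more over background, a median of 15 of the other 15 markers stood over 3 times background, as adult muscle taken with the tumours would need, and this is a candidate source. The test is weakened by AKT1_E17K replicates 4 and 5, where 14 markers each stood over the low background at 15.48 and 8.676 CPM of Acta1. In the libraries with Acta1 at 100 CPM or more, embryonic and perinatal myosins had 0.009441 of the counts of adult myosins. Single libraries among them ran from 0.000136 to 0.0307, a spread that crosses the limit set beforehand. Muscle differentiation of tumour cells or regenerating fibres thus cannot be told apart from adult muscle. No biological explanation by genotype was tested.

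For the other comparisons, chance cannot be excluded for AKT2_E17K against Pten_null (2618 genes at an unadjusted p under 0.05, highest other split 5774), AKT3_E17K against Pten_null (87, highest other 2934, 77 of 100 splits as many) or AKT1_E17K against AKT2_E17K (4704 at an adjusted p, highest other 6326, with AKT1_E17K replicate 2 grouped with AKT2_E17K replicates 1, 5 and 6). Splits that call more genes than the real one point to a structure of the libraries other than their groups. No other split reached the count for AKT1_E17K against AKT3_E17K (8053, highest other 0, 1 of 35 splits, the smallest share this design can give). The same held for the mean of the AKT groups (4417, highest other 86) and any difference (6457, highest other 5415), each 1 of 100 splits. For AKT2_E17K against AKT3_E17K the margin was narrow: 1902 genes at an unadjusted p, highest other 1787, again 1 of 35 splits, with 0 genes at an adjusted p. None of these shares was corrected over the 9 comparisons. Chance is thus argued against for these comparisons but not excluded, and background stays open for each.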

How the results depend on the processing

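The alternatives that correct for or avoid background, and thinning, were chosen after the data were seen; the others were set beforehand. No paired analysis was possible because replicate numbers do not pair tumours across groups. Simulated 2-fold changes were recovered in 0% to 6% of genes at the dispersions of these libraries, and 16-fold changes in 76% to 94%. At the same depths with a dispersion of 0.05, 2-fold changes were recovered in 34% to 56% and 4-fold changes in 76% to 100%. The spread between libraries thus limited recovery, while depth was not varied in these simulations and was not compared with it. The directions and calls that held are counts of passing genes within 1.5 times the value given, under RLE factors and the day of sacrifice for every comparison, and 0 calls for AKT3_E17K against Pten_null under every alternative run (87 at an unadjusted p under 0.05 in edgeR, 0 in DESeq2). Single genes were less stable with the day as a covariate. Of 13 higher genes named for AKT1_E17K against AKT2_E17K, 8 no longer passed.

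Counts of passing genes are given in the order AKT1_E17K against Pten_null, AKT1_E17K against AKT2_E17K, AKT1_E17K against AKT3_E17K, the mean of the AKT groups, and any difference. They were 25839, 15302, 23530, 14265 and 20226 in DESeq2, 27981, 18122, 25024, 15302 and 23664 without the filter, and 26088, 17376, 24122, 14454 and 22109 with a filter of 1 CPM in 4 libraries; these 3 test more genes. Limma-voom gave 7240 for AKT1_E17K against AKT2_E17K, 10476 for the mean and 10573 for any difference. With the keratinocyte and muscle scores as covariates they were 1, 4, 2, 0 and 3, with background subtracted 123, 0, 85, 1 and 0, with genes over 3 times background only 266, 0, 238, 0 and 96, with log2 background as a covariate 15, 353, 82, 0 and 8, and with counts thinned to 1 depth 2273, 324, 2020, 938 and 1421. Subtraction and the filter on background also test fewer genes, and thinning leaves fewer counts. The keratinocyte score comes from markers that were not over background, so it can follow background and is no separate measure of skin cells. For the covariates the cause was not otherwise tested. AKT1_E17K against AKT2_E17K gave 0 with only the groups compared and 0 in the 5 low-background libraries, which hold 1 AKT2_E17K library and so cannot test it, and the mean gave 1 without the libraries over 50% background, all 3 with fewer samples. DESeq2 gave 12 for Pten_null against Cdkn2a_null, 2 for AKT2_E17K against Pten_null and 11 for AKT2_E17K against AKT3_E17K, where edgeR gave 0 (555, 2618 and 1902 at an unadjusted p under 0.05). On simulated libraries for Pten_null against Cdkn2a_null, with 200 genes changed, DESeq2 called 14 unchanged genes and edgeR 2. DESeq2 also recovered more of the changed genes there, 74% against 58% at 8-fold. This does not tell how many of its 12 calls are false. For the other 2 comparisons the cause was not tested.

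Leaving out 1 library gave 6083 to 11132 genes for AKT1_E17K against Pten_null, 4223 to 6601 for AKT1_E17K against AKT2_E17K, 6709 to 9974 for AKT1_E17K against AKT3_E17K, 5197 to 8394 for any difference, and 2637 (without Pten_null replicate 1) to 6447 (without Pten_null replicate 4) for the mean. It gave 0 to 2 for AKT2_E17K against Pten_null and 0 to 1 for AKT2_E17K against AKT3_E17K, both highest without AKT2_E17K replicate 1. The correlation of AKT1_E17K and AKT2_E17K effects ran from 0.718 (without AKT2_E17K replicate 4) to 0.843 (without Pten_null replicate 4), and was 0.744 with a filter of 1 CPM in 4 libraries, 0.734 with split Pten_null libraries, 0.722 with background subtracted and 0.691 for genes over 3 times background. That of AKT1_E17K and AKT3_E17K ran from -0.104 (without Pten_null replicate 1) to 0.456 (without Pten_null replicate 4), and was also below 0 without Pten_null replicate 2 (-0.028), AKT3_E17K replicate 2 (-0.017) and AKT3_E17K replicate 4 (-0.012). That of AKT2_E17K and AKT3_E17K ran from 0.070 (without AKT3_E17K replicate 2) to 0.605 (without Pten_null replicate 4), and was 0.048 with split Pten_null libraries. The cause was not tested.

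Among named genes of AKT1_E17K against Pten_null, log2 fold changes turned with log2 background as a covariate for Acly (-0.26), Akt1 (-1.08), Atox1 (-0.69), Cdc6 (1.07), Cdh2 (-1.32), Cyc1 (-0.21), Dcn (-0.78), Eno1 (-0.68), Etv4 (-0.49), Fasn (-0.78), Gnl3 (-0.57), H2-Ab1 (-0.81), Ilk (-0.46), Insr (-0.0098), Irs2 (-0.51), Jun (-1.17), Ldlr (-0.096), Lep (0.078), Lmod1 (1.42), Mag (0.13), Pax5 (0.42), Phlda3 (-0.95), Pkm (-1.84), Rny1 (-1.14), Scarna6 (-0.39), Slc7a5 (-0.42), Snora73b (-0.89), Tln1 (-0.63), Tyrobp (-0.76) and Uqcrc2 (-0.15), and with the keratinocyte and muscle scores for Akt1 (-0.95), Atp2a1 (-0.66), Bcar1 (-0.072), Ccng1 (-0.36), Cdc6 (0.89), Cdh2 (-0.16), Col5a1 (-0.23), Dcn (-0.97), Fasn (-0.30), Gnl3 (-0.31), H2-Ab1 (-1.51), Ilk (-0.32), Irs2 (-0.32), Jun (-0.95), Ldlr (-0.12), Lum (-0.56), Phlda3 (-0.63), Pkm (-0.59), Rny1 (-2.48), Scarna6 (-0.93), Snora73b (-1.59), Srebf2 (-0.21), Tln1 (-0.70), Tnnt3 (-1.78) and Tyrobp (-0.41). Limma-voom turned Atp2a1 (-0.93), Myh1 (-0.82) and Tnnt3 (-0.0075). Against AKT3_E17K, log2 background turned Acly (-0.34), Fasn (-0.47) and Srebf1 (-0.95). Against AKT2_E17K it turned Lmod1 (1.04), limma-voom Myh1 (-0.029) and the scores Sned1 (-0.059). Background did not overlap between AKT1_E17K and Pten_null or AKT3_E17K. A sign turned by log2 background there depends on a slope assumed equal in all groups and does not settle the direction. The cause was not tested.

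List directions in camera turned too, given here with the list's median. Turned means a changed sign, whether or not the list passed in that setting. For AKT1_E17K against Pten_null these were B and plasma cell (0.94), FOXO targets (-0.63), MAPK pathway output (-0.70), amino acid response (ATF4) (-0.57), antigen presentation (-1.27), extracellular matrix (-0.99), focal adhesion and integrins (-0.60), glycolysis and hypoxia (-1.26), macrophage (-0.27), neural crest and dedifferentiated melanoma (-1.18), oxidative phosphorylation (-0.37), p53 targets (-0.42) and sterol and fatty acid synthesis (-0.20) with log2 background, FOXO targets (-0.54), antigen presentation (-1.40), extracellular matrix (-1.10), glycolysis and hypoxia (-0.75) and macrophage (-0.47) with the scores, antigen presentation (-0.085), glycolysis and hypoxia (-0.27), macrophage (0.24) and melanocyte pigmentation (0.90) with background subtracted, FOXO targets (-0.073), glycolysis and hypoxia (-0.29) and melanocyte pigmentation (1.08) with genes over background only, and skeletal muscle (-1.39) in limma-voom. For AKT1_E17K against AKT3_E17K, melanocyte pigmentation (2.34) turned with background subtracted and melanocyte pigmentation (2.22) with genes over background only, where fewer of its members are tested; log2 background turned oxidative phosphorylation (-0.61). For AKT1_E17K against AKT2_E17K, melanocyte pigmentation (0.46) turned with background subtracted and melanocyte pigmentation (0.50) with genes over background only, where fewer of its members are tested, B and plasma cell (0.96) and T and NK cell (-0.22) with log2 background, and B and plasma cell (6.04) in the 5 low-background libraries, which cannot test it. For Pten_null against Cdkn2a_null the scores turned antigen presentation (0.13), extracellular matrix (0.56), focal adhesion and integrins (0.27), oxidative phosphorylation (0.12) and p53 targets (-0.033). Log2 background turned extracellular matrix (0.45) for AKT2_E17K against Pten_null and glycolysis and hypoxia (0.038) for AKT2_E17K against AKT3_E17K, and extracellular matrix turned (-0.25) for AKT3_E17K against Pten_null without AKT3_E17K replicate 4, where leaving out 1 library gave up to 1.20 (without Pten_null replicate 4). The cause was not tested.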

Other observations

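These values were chosen after they were seen. Transcripts of the pigment pathway were near background in every group: Tyr, Tyrp1, Dct, Pmel and Mlana stood over background in 0 libraries. In the 4 AKT1_E17K libraries, which have the least background, Tyr had 5 counts and Dct 14 in all, against 7268 of Sox10, 523 of Mitf and 11522 of Axl, a receptor gene of dedifferentiated melanoma. Axl stood over background in 5 of 5 Cdkn2a_null, 4 of 5 Pten_null, 4 of 4 AKT1_E17K, 4 of 4 AKT2_E17K and 3 of 4 AKT3_E17K libraries.

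Mitochondrial genes held 10.5 ± 5.54% of counts (SD, n = 4) in AKT1_E17K, 9.78 ± 4.50% (SD, n = 4) in AKT2_E17K, 4.59 ± 3.63% (SD, n = 4) in AKT3_E17K, 2.60 ± 2.58% (SD, n = 5) in Pten_null and 3.79 ± 2.56% (SD, n = 5) in Cdkn2a_null. Against Pten_null the exact permutation p was 0.0238 for AKT1_E17K and for AKT2_E17K (two-sided, adjusted 0.111 over 70 tests). These are shares of all counts, so they fall where others rise: satellite-like genes held 0.582 ± 0.339% (SD, n = 4) in AKT1_E17K, 9.30 ± 13.4% (SD, n = 4) in AKT2_E17K and 31.0 ± 23.1% (SD, n = 5) in Pten_null, and background differed likewise.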
